A study of Mus musculus with 6 samples.

How the data were processed

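Undifferentiated spermatogonia, the cell population of the mouse testis that holds the spermatogonial stem cells, were grown on inactivated embryonic fibroblast feeders. Their medium held GDNF (10 ng/ml), bFGF (10 ng/ml), EGF (20 ng/ml) and insulin (25 µg/ml). The cells carried Sall4 alleles flanked by loxP sites and Ubc-CreER, a Cre recombinase that is expressed broadly and enters the nucleus when it binds 4-hydroxytamoxifen. Per the labels, treated cultures received 0.2 µM 4-hydroxytamoxifen for 4 days and regular medium for a further 4 days. The series text words the harvest as 4 days after treatment, and the labels do not settle whether this counts from the start or the end of exposure. Before RNA extraction the spermatogonia were sorted on the surface protein EpCAM to separate them from the feeders. Labelled cRNA was made from 0.1 µg of total RNA per sample and hybridised in 1 colour (Cy3) to 6 arrays on 1 slide, with 1 scan date.

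The deposited scanner files hold spot intensities. Per the file headers and the submitters' processing notes, these intensities came from Agilent Feature Extraction 11.0.1.1, which subtracted background and removed spatial trends within each array but did not scale arrays against one another. A separate table of the whole series, deposited by the authors, holds log2 values per probe. Its method is not given in the sources used here. Its 6 columns had medians of 6.476 to 6.482 and differed by at most 0.0818 at any one rank, as after quantile normalisation. They correlated at r of at least 0.9988 with the log2 median pixel intensity of the same array, so scale and direction were settled from the values, and the centring and background treatment were not. This table was used as an alternative only.

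For the main analysis, the background-subtracted intensity was converted to log2 and each array's 75th percentile over non-control probes was subtracted. Control spots were left out, as were 17 probes with an outlier spot, and repeated spots of a probe were averaged. No spot was saturated (0 on each array). Of 55681 non-control probes, 27235 (48.9%) received a gene symbol by matching the RefSeq accession in the scanner file, without its version, to a RefSeq gene table of assembly GRCm38.p6. The other probes kept their accession or array name and were tested but not named. The array's own build is mm9, so no coordinates are given. Each gene was represented by its brightest probe over the 6 arrays, and genes were tested where that probe was well above background on at least 3 arrays. This left 24923 of 37066 genes, of which 15448 had a symbol. Among 5932 tested genes with several tested probes, 1934 had at least 1 probe of opposite sign. Among the genes past the threshold, 24 had several probes and 2 of these had a probe of opposite sign, Sall4 being 1 of the 2.

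The only comparison was 3 tamoxifen against 3 vehicle samples, fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Values are log2 differences, tamoxifen minus vehicle, with the standard error of the fit. A gene not well above background on any array of 1 group is given as a lower bound on its fold, the bright group's mean against the higher of the dim probe's own value and the lowest signal among probes well above background. The series text says that 3 independently derived cultures were each given vehicle or drug. The titles number the samples 1 to 3 in each group without saying that a number marks a culture.

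Whether equal numbers pair the samples was checked from the correlation of deviations from the group means, across genes, which are not independent replicates. Over all 24923 genes the same-numbered pairs gave r of 0.162, -0.486 and -0.100, so the check did not reach 0.1 in every pair. The 12461 genes above the median level were examined after that result was seen, and gave r of 0.358, 0.422 and 0.345, with values from -0.351 to -0.0122 for the other pairings. The 12462 other genes gave 0.185, -0.492 and -0.101 for the same-numbered pairs. Deviations sum to 0 within a group, so positive values for equal numbers force negative ones among the other pairings. The pairing was accepted on the check of brighter genes and the series text together. The counts of both fits had been seen by then, so this was not a blind choice, and gene and list counts with the replicate number as a block are given as well. A reading on the first check alone would treat the numbers as names only. Standard errors and p-values are from the fit without the block unless a block is named.

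Gene lists (35, all with at least 5 tested members) were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and limma's fry were run beside it. Camera sets a list against the other genes, while list medians and counts of signs are given against 0. The median log2 difference over all tested genes was -0.06, so a list median near that value is no shift against other genes. The lists covered undifferentiated spermatogonia, spermatogonial differentiation, meiosis, spermatids, germ cell identity and the piRNA pathway, pluripotency, SALL and PLZF family factors, forkhead factors and Hox genes. Signalling lists were GDNF and FGF components, ERK feedback and immediate targets, mTORC1 regulators and sestrins, Wnt, retinoic acid, and TGF-beta and BMP. Lists for cell state were proliferation, cell cycle inhibitors, apoptosis regulators, p53 targets, DNA damage repair, heat shock and unfolded protein response, interferon-stimulated genes, glycolysis, cholesterol synthesis, and cell adhesion and integrins. Chromatin lists were polycomb, NuRD, DNA methylation and heterochromatin, and imprinted genes. Markers of other cell types were those of embryonic fibroblasts, Sertoli cells, Leydig cells, macrophages and endothelium. A last list held genes the study is known to have examined.

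Before the data were examined, the groups, the test, the gene lists, the alternatives and a rule for naming genes were fixed. Under that rule the text names Sall4, 11 genes known to interest the study, and up to 12 genes in each direction with the largest change among those past the threshold, well above background on all arrays and of 1 sign in all 3 same-numbered pairs. It also names up to 5 bounded genes in each direction and, per list, up to 4 members past the threshold or else the 2 with the largest change. The other settings fixed then were the replicate number as a block, normexp background correction with an offset of 50, quantile normalisation, median centring, no filter and a stricter filter on dim probes, the mean of all probes, an intensity trend with a robust prior, slide row as a term or a random block, the series table, array weights, an unmoderated linear-model test, all probes tested separately, and leaving out each sample. Normexp was planned on the mean spot intensity, a column not used here, and ran on the median spot intensity. The block with an intensity trend and robust prior, the block on the series table, and slide column as a covariate were added after seeing the data.

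The fits were also run on simulated arrays with the 24923 genes and known changes. With 3 samples a group, the main test recovered 32 of 100 genes changed 2-fold and 70 of 100 changed 4-fold, and called 6 of 24701 unchanged genes. The fit with the replicate block recovered 0 of 100 at both sizes. No differences between cultures were simulated, so the block had nothing to remove and this does not measure what it recovers from paired samples. A count of 0 in that form of the fit does not by itself exclude change. A list of 22 members shifted by -0.50 was called by camera, and 0 of 34 unshifted lists were. The simulated noise was independent between genes. It therefore cannot show how often camera calls an unshifted list when genes are correlated. The number of arrays limits the precision of every value.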

Results

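RNA from cultured undifferentiated spermatogonia was measured on 1-colour microarrays in 6 samples, 3 given vehicle and 3 given 4-hydroxytamoxifen to delete Sall4, which encodes a zinc finger transcription factor of undifferentiated spermatogonia and pluripotent cells. The samples came from 3 independently derived cultures. No sample with 4-hydroxytamoxifen or active Cre but intact Sall4 was analysed here. Between 29705 (53.4%) and 36997 (66.4%) of the 55681 probes were well above background on each array, and the 75th percentile of signal lay between 388.1 and 427.4. The level of dim probes differed more, with medians from 24.2 (tamoxifen replicate 3) to 62.0 (tamoxifen replicate 2), and followed the array's column on the slide rather than the group. Across genes, arrays correlated pairwise at r of 0.960 to 0.993. The first principal component (65.9% of variance) did not part the groups, and the second (15.1%) did.

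The targeted gene was examined first. Of 3 Sall4 probes, 2 were lower and 1 was higher in the tamoxifen samples. Probe A_51_P145260 went from -0.95 ± 0.05 in vehicle to -2.10 ± 0.32 in tamoxifen (mean ± SD of log2 level relative to the array's 75th percentile, n = 3), a log2 difference of -1.16 (SE 0.177, limma adjusted p = 0.0766 with all probes tested separately). Probe A_55_P2173546 was well above background in all 3 vehicle samples but in only 1 tamoxifen sample, replicate 2, so only its sign is given (limma adjusted p = 0.208). Its size depended on the setting, and its limma adjusted p ran from 0.0106 to 0.468 over the alternatives. The brightest probe, A_51_P349087, went the other way, from 2.94 ± 0.03 to 3.91 ± 0.15, by 0.97 (SE 0.103). It passed in the gene-level fit (limma adjusted p = 0.0425) and missed in the probe-level fit (adjusted p = 0.0565). In the gene-level fit it also missed with the replicate block (0.165), without vehicle replicate 1, 2 or 3 (0.165, 0.161 and 0.205) and without tamoxifen replicate 1, 2 or 3 (0.172, 0.0831 and 0.168). Over the gene-level alternatives that kept this probe the limma adjusted p ran from 0.00208 to 0.205. With the 3 probes averaged the sign reversed, at -0.80 (0.235). The same-numbered differences were -1.26, -0.76 and -1.44 for the first probe and 1.103, 0.86 and 0.95 for the brightest, and for A_55_P2173546 -0.68 in replicate 2 and negative in the other pairs. Where the probes lie relative to the deleted part of Sall4 is not given in the sources used here, so a probe outside it would check nothing, and the direction of every change below rests on the sample labels.

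**Figure D1:**
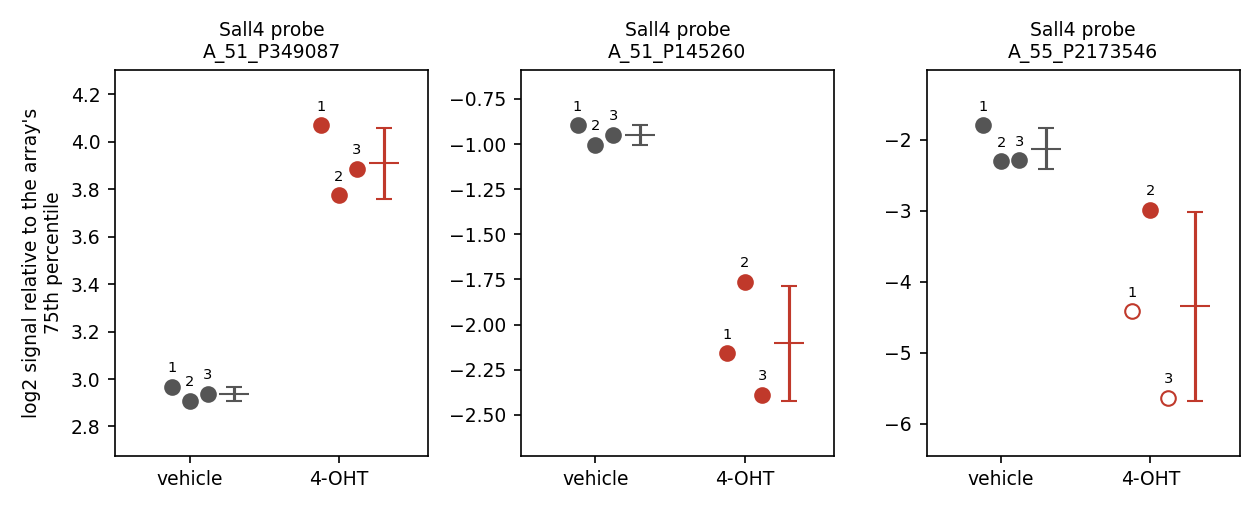
Log2 signal of the 3 Sall4 probes relative to the array's 75th percentile, 1 panel per probe, for the vehicle and 4-hydroxytamoxifen (4-OHT) samples; points are samples with their replicate number, horizontal lines are means and bars 1 SD (n = 3), and open points are not well above background. Probe A_51_P349087 was higher by 0.97 in tamoxifen samples, while A_51_P145260 was lower, at -1.16, as was A_55_P2173546, which was not well above background in 2 tamoxifen samples.

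The comparison of tamoxifen with vehicle asked which genes depend on Sall4 in undifferentiated spermatogonia. Gene values below are from the fit without the replicate block unless a block is named. With the block 0 genes passed (limma, smallest adjusted p 0.165, 4676 genes at unadjusted p under 0.05). Genes for glucose uptake and breakdown fell, among them Pfkl, the liver form of phosphofructokinase, by 2.22 on the log2 scale (SE 0.129), Slc2a1, the glucose transporter GLUT1, by 1.36 (SE 0.118), and Slc16a3, a lactate exporter, by 1.50 (SE 0.110). Ddit4, which encodes an inhibitor of the growth regulator mTORC1, fell by 2.13 (SE 0.116), and Ankrd37, a gene induced by hypoxia, by 2.52 (SE 0.192), all with n = 3 per group and limma adjusted p from 0.0308 to 0.0361. Among the largest rises were those of Rtp4, an interferon-inducible receptor chaperone, by 3.27 (SE 0.162), Tnfsf13b, the B cell survival factor BAFF, by 3.12 (SE 0.241), Pdcd1lg2, the checkpoint ligand PD-L2, by 2.02 (SE 0.164), and Ly96, the co-receptor of the endotoxin receptor TLR4, by 1.81 (SE 0.190). Their limma adjusted p lay between 0.0308 and 0.0424. These 4 genes were picked by the size of their change, not as a group. Interferon-stimulated genes as a list passed (median 0.23, camera adjusted p = 0.00822), but not with an estimated correlation (adjusted p = 0.426) or without tamoxifen replicate 1 (0.141). Macrophage markers did not pass (median 0.37, 9 of 11 positive, 0.242).

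Other large rises were those of Dct, an enzyme of melanin synthesis (3.19, SE 0.354), Enpp3, an ectonucleotidase (2.11), Arhgef28, a Rho guanine nucleotide exchange factor (1.99), Cpne4 (1.96), Ap3b2, a subunit of the neuronal AP-3 adaptor (1.89), Pla2g10, a secreted phospholipase (1.89), Mc5r, a melanocortin receptor (1.88), and Dcaf8l (1.86). Falls of similar size were those of Upp1, uridine phosphorylase (-2.14), Krt19, a keratin (-2.10), Pcsk2, a prohormone convertase (-1.90), Ly6g6e (-1.70), Dmrt2, a DM-domain transcription factor (-1.70), Asb7 (-1.69) and Tmcc3 (-1.36). The other probes of Upp1 and Tmcc3 stood at -1.38 and -0.87 (limma adjusted p = 0.152 and 0.111 with all probes tested separately). Those of Dct and Arhgef28 stood at 3.115 and 1.53. Several rises were of dim probes and their size depended on the scaling. On the series table Rtp4 stood at 2.43, Tnfsf13b at 2.33, Enpp3 at 1.53, Ly96 at 1.40, Pdcd1lg2 at 1.30, Cpne4 at 1.26 and Mc5r at 1.07, and the lowest value over the alternatives was 1.22 for Pdcd1lg2, 1.14 for Cpne4 and 0.99 for Mc5r. The limma adjusted p of the 15 genes first named here lay below 0.05, at 0.0308 for Dcaf8l and up to 0.0478 for Ly6g6e. Pcdhac2, a protocadherin, was not well above background in any vehicle sample and was at least 2.02-fold higher in tamoxifen samples (limma adjusted p = 0.0339). Htr1d, a serotonin receptor, and Gpr85, an orphan receptor, were not well above background in any tamoxifen sample and were at least 1.45-fold and at least 1.33-fold lower (adjusted p = 0.0455 and 0.0339). These bounded genes depended on the setting, and the bounds hold for the main scaling only. On the series table Pcdhac2 stood at 0.85 (limma adjusted p = 0.0169), and its lowest value over the alternatives was 0.73, both under 2-fold. On the series table Htr1d stood at -0.13 (limma adjusted p = 0.735) and Gpr85 at -0.45 (0.156), with an intensity trend their adjusted p was 0.601 and 0.288, and they missed in 17 and 16 of 20 alternatives, Pcdhac2 in 11.

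In all, 149 of 24923 genes passed the threshold, 92 higher and 57 lower in tamoxifen samples, and 124 of them had a gene symbol. At least 2-fold changes were 66 rises and 34 falls (100 genes). At unadjusted p under 0.05 there were 4668 genes where independent tests give 1246.2 by chance, but a split of the samples by slide column (1 and 2 against 3 and 4) in place of treatment gave 4056, a comparison chosen after the result was seen. In the real split the groups did not overlap in 6646 genes (26.7%, chance share 10%). The calls lay close to the threshold, the smallest limma adjusted p being 0.0308. With the replicate number as a block 0 genes passed (limma, smallest adjusted p 0.165, 4676 genes at unadjusted p under 0.05), as did 0 with slide row as a term (0.160, 3503 genes) and 0 without the filter on dim probes (0.0990, 3938 genes), while slide column as a covariate left 6. Leaving out any 1 sample also left 0, with a smallest limma adjusted p of 0.158, 0.100 and 0.190 without vehicle replicate 1, 2 and 3 and of 0.138, 0.0784 and 0.132 without tamoxifen replicate 1, 2 and 3, and 3075 to 5652 genes at unadjusted p under 0.05.

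**Figure D2:**
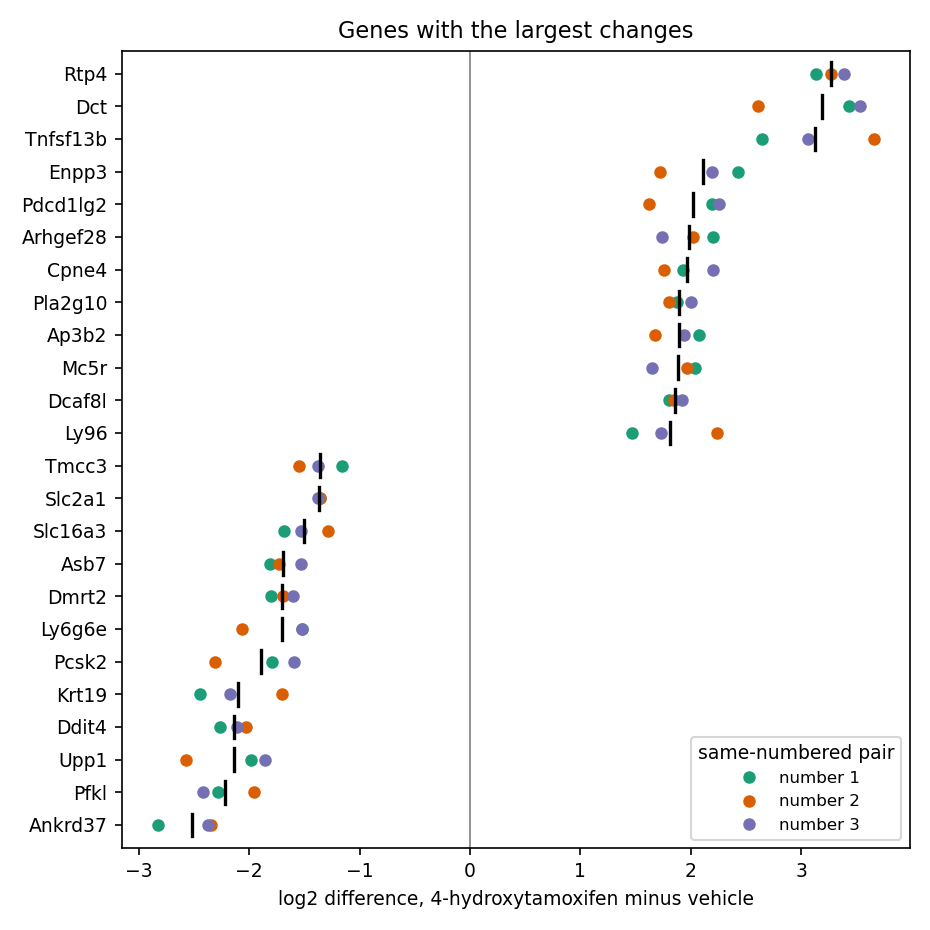
Log2 difference, tamoxifen minus vehicle, of the 12 rising and 12 falling genes named by rule; coloured points are the 3 same-numbered pairs and black bars the mean (n = 3 per group). Rtp4 lies at 3.27 and Ankrd37 at -2.52; genes were chosen to have 1 sign in all 3 pairs.

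Glycolysis was the list with the smallest p. Its 22 measured members had a median log2 difference of -0.54, 21 were lower, and 15 fell when adjusted over the list alone, as 4 did over all genes (Pfkl, Slc16a3, Slc2a1 and Pgk1, phosphoglycerate kinase, at -0.91, SE 0.0881). Camera gave an adjusted p of 1.98e-12 at the preset correlation, and adjusted p = 0.426 with an estimated correlation. The list's median was -0.65, -0.61 and -0.62 in the 3 same-numbered pairs. Cholesterol synthesis genes were lower as a group, with a median of -0.31 over 23 members, of which 20 were negative, 12 fell when adjusted over the list alone and 0 over all genes (limma; 13 members at unadjusted p under 0.05). With the replicate block 1 passed over the list alone, in place of 12. The sterol isomerase gene Ebp stood at -0.89 (limma adjusted p = 0.0535) and the lanosterol demethylase gene Cyp51 at -0.59 (0.145). Camera's adjusted p was 3.01e-05, and adjusted p = 0.426 with an estimated correlation.

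Hox genes, the homeobox genes that pattern the body axis, had a median of 0.62 over 33 measured members, and of 0.28 (with array weights) to 0.80 over the alternatives. Of these 26 were positive, 13 rose when adjusted over the list alone and 2 over all genes, Hoxb4 by 1.80 (SE 0.195) and Hoxb2 by 1.56 (SE 0.184), at limma adjusted p = 0.0455 and 0.0478. Camera gave an adjusted p of 1.39e-06, and adjusted p = 0.426 with an estimated correlation. Markers of embryonic fibroblasts, the feeder cells that the EpCAM sort was meant to remove, were also higher, with a median of 0.32 over 29 members, 22 of them positive (camera adjusted p = 2.61e-06, and adjusted p = 0.426 with an estimated correlation). Of these, 5 rose when adjusted over the list alone and 1 over all genes, the matrix protease gene Mmp2, by 0.81 (SE 0.0920). Between the upper and lower slide rows the median of the Hox list was 0.93 and 0.41, and that of the fibroblast markers 0.13 and 0.52. Each row value rests on 1 sample in a group. Tamoxifen replicate 3 was the only tamoxifen sample in the upper row, and vehicle replicate 3 the only vehicle sample in the lower.

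**Figure D3:**
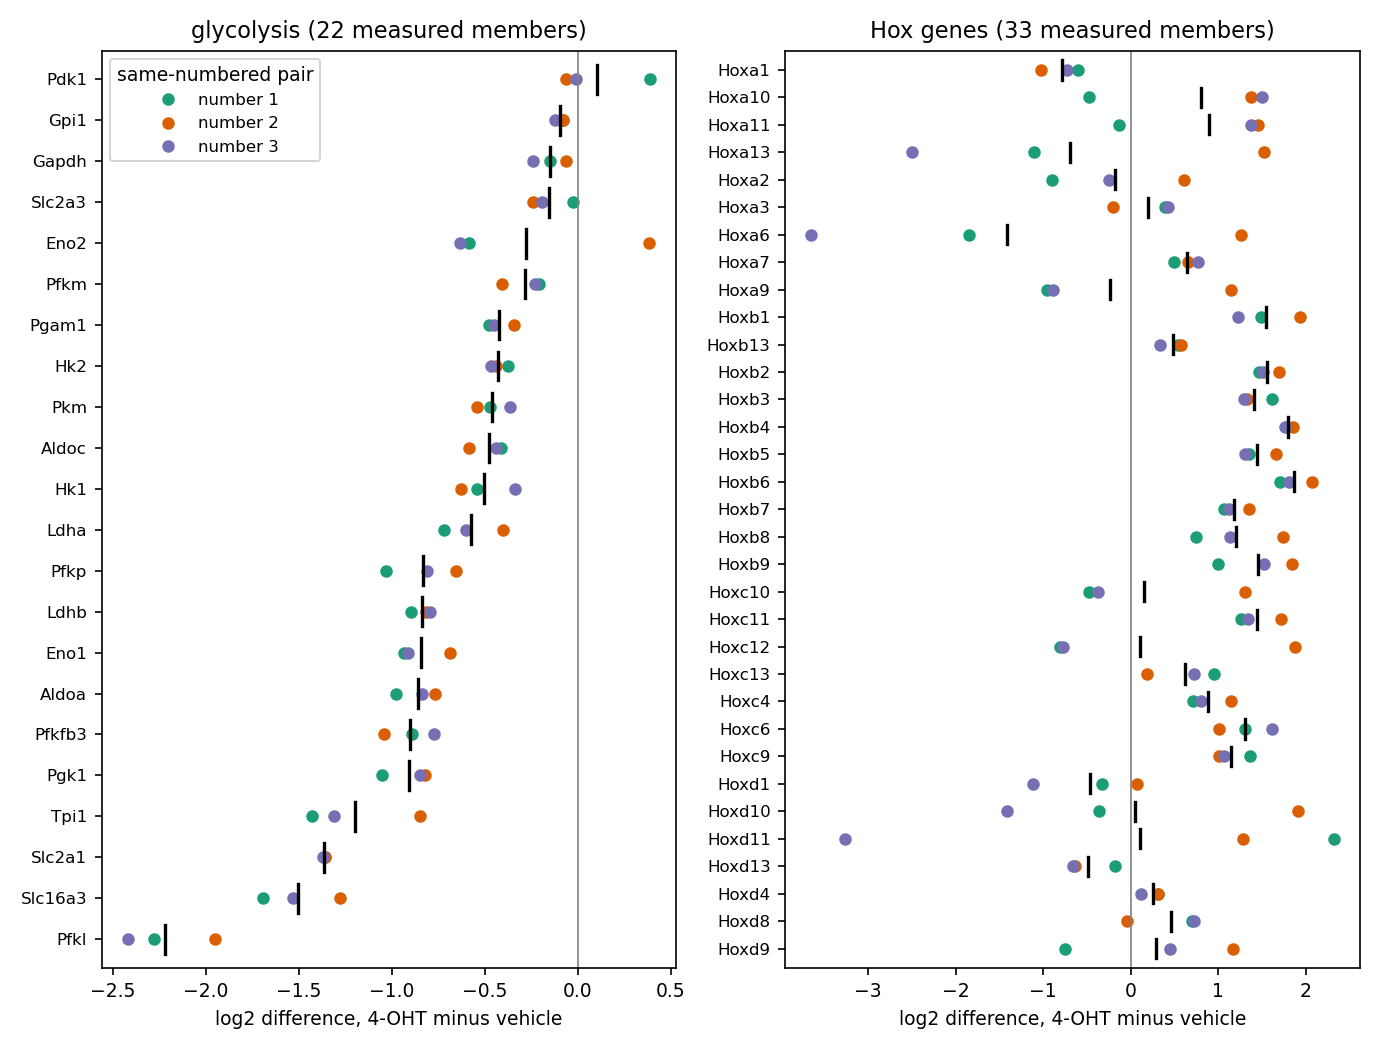
Log2 difference, tamoxifen minus vehicle, of each measured glycolysis gene (left, 22 genes) and Hox gene (right, 33 genes); coloured points are the 3 same-numbered pairs and black bars the mean. Of the glycolysis genes 21 lie below 0, and of the Hox genes 26 lie above it.

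Feedback regulators and immediate targets of the ERK kinase pathway were higher, with a median of 0.36 over 30 members (camera adjusted p = 1.39e-06, and adjusted p = 0.426 with an estimated correlation). Of these, 8 rose when adjusted over the list alone and 3 over all genes, namely Dusp4, a phosphatase that inactivates ERK (0.96, SE 0.110), the immediate early gene Ier2 (1.11, SE 0.107) and the ETS factor gene Etv1 (2.14-fold, SE 0.0939 on the log2 scale). Etv1 was dim, with a vehicle mean of -3.77, stood at 0.45 on the series table (limma adjusted p = 0.107), had an adjusted p of 0.0918 with an intensity trend, and missed in 16 of 21 alternatives. Targets of the tumour suppressor p53 had a median of 0.35 over 33 members, of which 9 rose and 1 fell when adjusted over the list alone (camera adjusted p = 3.01e-05, and adjusted p = 0.426 with an estimated correlation). The member that passed over all genes went against the list: Sesn1, a sestrin that restrains mTORC1, fell by 1.00 (SE 0.108). Interferon-stimulated genes had a median of 0.23 over 23 members, 5 of which rose when adjusted over the list alone and 0 over all genes (limma; 6 at unadjusted p under 0.05). Rsad2 stood at 1.57 (limma adjusted p = 0.0896) and Isg15 at 1.32 (0.0929). Camera's adjusted p for this list was 0.00822, adjusted p = 0.426 with an estimated correlation, and 0.141 without tamoxifen replicate 1. The list's median was -0.04 and 0.29 in the upper and lower slide row, each with only 1 sample in a group. This median fell to 0.09 without tamoxifen replicate 1 and 0.08 without vehicle replicate 3.

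The other 4 downward shifts were smaller, and the median over all tested genes was -0.06. Each of these lists had a smaller unadjusted camera p in the split by slide row than by treatment. This was 8.57e-07 against 0.000327 for proliferation, 0.00913 against 0.0101 for differentiation, 0.0069 against 0.00933 for heat shock and 0.000139 against 0.00998 for repair genes. The rows held unequal numbers of each treatment, so slide row and treatment are only partly told apart here. Proliferation genes had a median of -0.18 over 38 members, 32 of them negative, with 0 past the threshold over all genes or adjusted over the list alone (limma; 6 at unadjusted p under 0.05). The replication genes Mcm4 and Cdc6 stood at -0.52 and -0.44 (limma adjusted p = 0.0976 and 0.0924). Camera's adjusted p was 0.00163, and adjusted p = 0.74 with an estimated correlation. Genes of spermatogonial differentiation had a median of -0.20 over 18 members (camera adjusted p = 0.0320, and adjusted p = 0.426 with an estimated correlation). When adjusted over the list alone 2 rose and 4 fell, and over all genes Dmrtb1, a DM-domain factor that controls the switch from mitosis to meiosis, rose by 1.39 (SE 0.120) while the DNA methyltransferase gene Dnmt3b fell by 0.75 (SE 0.0862). Heat shock and unfolded protein response genes had a median of -0.14 over 19 members, of which 2 rose and 6 fell when adjusted over the list alone and Herpud1 fell over all genes, by 0.71 (SE 0.0842). DNA damage repair genes had a median of -0.12 over 30 members, with 0 past either threshold (limma; 6 at unadjusted p under 0.05). These included Exo1 at -0.47 (limma adjusted p = 0.134), and Chek1, which was not well above background in any tamoxifen sample and is given no size (0.197). Both lists had a camera adjusted p of 0.0320, and adjusted p = 0.426 with an estimated correlation. Random gene lists matched on mean level, drawn after the results were seen, had a median of -0.05 for repair and -0.03 for heat shock genes. With the replicate block the camera adjusted p was 0.0837 for heat shock and 0.0784 for repair genes. Without tamoxifen replicate 2 it was 0.806 for proliferation, 0.515 for differentiation, 0.454 for heat shock and 0.515 for repair genes, and without vehicle replicate 2 it was 0.104 and 0.0907 for the latter pair.

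The replicate block also changed how many members passed when adjusted over the list alone. Heat shock genes went from 8 to 4, undifferentiated spermatogonia genes from 7 to 1, Wnt genes from 11 to 5, TGF-beta and BMP genes from 4 to 0 (limma, 8 at unadjusted p under 0.05 without the block), and fibroblast markers, interferon-stimulated genes and adhesion genes each from 5 to 3. Losses of 1 were from 4 to 3 for mTORC1 regulators, 2 to 1 for DNA methylation genes and 1 to 0 for endothelial markers (2 at unadjusted p under 0.05 without the block). Increases were from 8 to 13 for ERK, 13 to 16 for Hox, 15 to 16 for glycolysis, 10 to 12 for p53, 6 to 7 for differentiation, 4 to 8 for retinoic acid, 8 to 10 for cell cycle inhibitor and 0 to 1 for apoptosis genes (8 at unadjusted p under 0.05 without the block). Pluripotency (9), imprinted (5), study (4), macrophage (1), forkhead (1) and SALL and PLZF family genes (1) kept their counts.

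**Figure D4:**
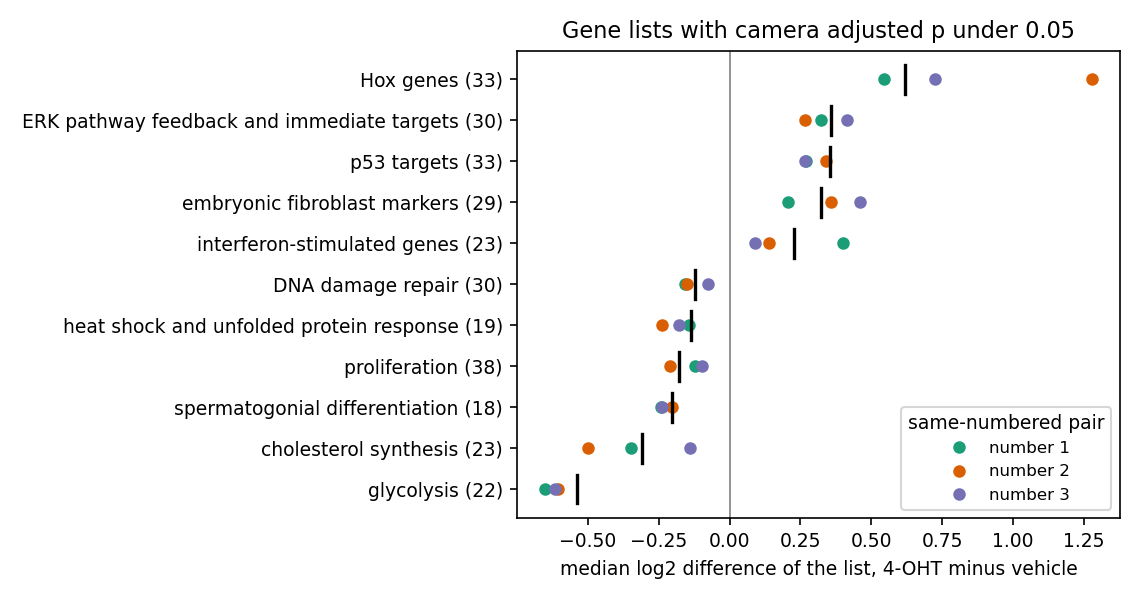
Median log2 difference, tamoxifen minus vehicle, of the 11 gene lists with a camera adjusted p under 0.05 at the preset correlation, with the number of measured members in brackets; coloured points are the medians in the 3 same-numbered pairs and black bars the median of the mean differences. Medians range from -0.54 for glycolysis to 0.62 for Hox genes.

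The remaining 24 lists did not pass, and their medians are to be read against the median of -0.06 over all tested genes. Genes the study is known to have examined gave mixed results, and since they are known from the study itself their list is not independent evidence of a direction. Besides Sall4, Dusp4 and Ddit4, the forkhead gene Foxl1 stood at 1.25 (SE 0.258, limma adjusted p = 0.0975), the receptor gene Kit, a marker of differentiating spermatogonia, at -0.72 (SE 0.206, 0.162) and the Sall4 paralogue Sall1 at -0.16 (0.778). Zbtb16, the transcription factor PLZF, stood at -0.22 (0.604). Among genes of GDNF response, the receptor genes Ret and Gfra1 stood at -0.51 (0.250) and -0.02 (0.973), and the transcription factor genes Lhx1, Etv5 and Bcl6b at 0.50 (0.311), 0.02 (0.961) and 0.12 (0.819). The list of 6 study genes had a median of 0.40 (camera adjusted p = 0.112), with 3 rises and 1 fall when adjusted over the list alone and 2 rises over all genes. Over the alternatives its median ran from -0.19 to 0.50. Sall4 counts among the rises by its brightest probe, against which its other probes went. Undifferentiated spermatogonia genes had a median of -0.03 over 30 members (camera adjusted p = 0.242), of which 1 rose and 6 fell when adjusted over the list alone and Upp1 fell over all genes.

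Pluripotency genes had a median of -0.33 over 22 members (camera adjusted p = 0.102), with 1 rise and 8 falls when adjusted over the list alone and 0 over all genes (limma; 10 at unadjusted p under 0.05). Tdgf1, a Nodal co-receptor, stood at -1.71 (limma adjusted p = 0.128). Prdm14, not well above background on every array, is given no size (0.160). Among mTORC1 regulators and sestrins (median -0.16, camera adjusted p = 0.0759) Ddit4 and Sesn1 fell over all genes. Dnmt3b fell in the DNA methylation and heterochromatin list (median -0.18, camera adjusted p = 0.0501, and 0.00887 to 0.644 over its alternatives). The laminin gene Lama5 fell by 0.84 and the claudin gene Cldn3 by 0.81 in the adhesion and integrin list (median -0.09, adjusted p = 0.0837). Cell cycle inhibitors went both ways (median -0.17, adjusted p = 0.617): Cdkn2d, an inhibitor of the CDK4 kinase, fell by 1.08 (SE 0.0881), the cyclin gene Ccng2 fell by 0.89 (SE 0.0928) and the stress gene Gadd45g rose by 0.91 (SE 0.108), at limma adjusted p = 0.0361, 0.0424 and 0.0478. Wnt pathway genes (median -0.10, adjusted p = 0.621) had 4 rises and 7 falls when adjusted over the list alone, with the ligand genes Wnt10a and Wnt5a at 1.21 and 0.92 (limma adjusted p = 0.0553 and 0.0517).

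Of the other chromatin lists none passed. In the polycomb list (median -0.10, camera adjusted p = 0.211) the histone methyltransferase gene Ezh2 stood at -0.55 (limma adjusted p = 0.0982) and Pcgf3 at 0.50 (0.233). In the NuRD deacetylase complex (median -0.01, camera adjusted p = 0.431) Rbbp4 stood at -0.52 (0.0980) and Gatad2b at -0.32 (0.169). The other probe of Rbbp4 stood at -0.05 (limma adjusted p = 0.916 with all probes tested separately). Among imprinted genes (median -0.09, camera adjusted p = 0.869) Rasgrf1 (limma adjusted p = 0.0765) and Peg10 (0.489) were not well above background on every array and are given no size, with 2 rises and 3 falls when adjusted over the list alone. The SALL and PLZF family (median 0.10, camera adjusted p = 0.272) held 1 gene past the threshold, Sall4 itself. Among forkhead factors (median -0.14, camera adjusted p = 0.491) Foxd2 stood at -0.84 (0.0558).

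Signalling and death genes were also mixed. In the GDNF and FGF list (median -0.06, camera adjusted p = 0.459) the PI3 kinase subunit gene Pik3r1 stood at -0.92 (limma adjusted p = 0.0786) and the receptor gene Erbb3 at 0.86 (0.103). Aldh1a1, an enzyme that makes retinoic acid, stood at 1.32 (0.114) and Stra8, which retinoic acid induces, at -0.95 (0.119). Camera gave the retinoic acid list an upward direction (adjusted p = 0.857) with a mean of 0.02 and a median of -0.05, and 1 member rose and 3 fell when adjusted over the list alone. The TGF-beta and BMP list likewise had an upward direction (camera adjusted p = 0.908), a mean of 0.03 and a median of -0.07, with the BMP target Id1 at 1.05 (0.0580) and Lefty1 at 0.61 (0.466). Among apoptosis regulators (median 0.06, camera adjusted p = 0.242) Pmaip1, the p53 target NOXA, stood at 0.78 (0.133) and Bmf at -0.66 (0.148).

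Lists of later germ cell stages and other cell types of the testis did not pass. Meiosis genes had a median of -0.06 (camera adjusted p = 0.418), with Tex15 at -0.51 (limma adjusted p = 0.147). The named genes Hsf2bp (limma adjusted p = 0.223), Prm1 (0.497), Odf1 (0.793), Cst12 (0.585), Aard (0.318) and Ptprc (0.432) were not well above background on every array and are given no size. The germ cell identity and piRNA list had a median of -0.03, a mean of 0.02 and an upward camera direction (adjusted p = 0.857), with Tdrd6 at 0.72 (0.138) and Dppa3 at 0.74 (0.288). Spermatid genes had an upward camera direction (adjusted p = 0.908) against a median of -0.17 and a mean of -0.25, Prm1, a protamine gene, and Odf1 among them. Sertoli markers, Cst12 and Aard among them, had a median of -0.09 (camera adjusted p = 0.908). Leydig markers (median -0.09, 0.908) included Star at 0.24 (0.601), with its other probe at -0.23, and Cyp17a1 at -0.22 (0.681). Endothelial markers (median -0.01, 0.908) included Erg at -0.77 (0.0992) and Eng at 0.44 (0.158). Macrophage markers (median 0.37 over 11 members, camera adjusted p = 0.242, and 0.0393 to 0.776 over alternatives) included the pan-leukocyte gene Ptprc and the mannose receptor gene Mrc1 at -0.84 (0.0886). The median of these markers ran from 0.0335 to 0.604 over the alternatives. It was 0.198, 0.865 and -0.192 in the 3 same-numbered pairs.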

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

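Among the settings tried, the block on the series table, the block with an intensity trend and slide column as a covariate were chosen only after the main result was seen. Pfkl, Ddit4 and Rtp4 kept their direction in all 21 alternatives in which named genes were followed. All 43 named genes past the threshold other than Sall4 did so in each of these alternatives that tested them. Whether they passed depended on the setting. The 149 changed genes became 464 with normexp correction, 336 with quantile normalisation, 788 on probes well above background on all 6 arrays, 1446 with an intensity trend and robust prior, 929 on the series table and 3296 with array weights, but 3 with an unmoderated test, 49 with all probes tested separately and 6 with slide column as a covariate. It was 0 without the filter on dim probes (limma, 3938 genes at unadjusted p under 0.05), 0 with slide row as a term (3503) and 0 without any 1 sample (3075 to 5652). The 100 genes changed at least 2-fold became 205 on all 6 arrays, 257 with the trend, 505 with weights, 6 with slide column and 0 wherever the first count was 0. In the intensity-trend and weighted fits falls outnumbered rises, with 45.5% and 46.3% of calls upward against 61.7%. The cause was not tested.

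With the replicate number as a block, the paired form of the comparison, both gene counts were 0 (limma, 4676 genes at unadjusted p under 0.05), and with a block and an intensity trend they were 2640 and 289. The block on the series table gave 329. The block gave 9 lists in place of 11, losing heat shock (camera adjusted p = 0.0837) and DNA repair genes (0.0784), and changed no other list call. The brightest Sall4 probe differed by 0.97 (adjusted p = 0.165) with the block, 0.97 (0.137) without the filter, 0.97 (0.163) with slide row, 0.95 (0.0690) with slide column and 0.89 to 1.04 with 1 sample left out (without tamoxifen replicate 1 and 2). It was -0.80 (0.235) when Sall4's 3 probes were averaged, and over all alternatives the adjusted p of Sall4 ran from 0.00208 to 0.235.

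The 11 shifted lists became 17 with slide column, 0 with an estimated correlation (camera, smallest adjusted p 0.426, 1 list at unadjusted p under 0.05, glycolysis at 0.0323), 9 by fry's directional test, 32 by its mixed test, which ignores direction, 7 without tamoxifen replicate 2 and 16 without tamoxifen replicate 3. The directional fry test kept 5 of the 11, lost Hox (adjusted p = 0.0823), fibroblast (0.0721), cholesterol (0.0643), interferon (0.0925), differentiation (0.0783) and proliferation genes (0.193), and added 4 others. Glycolysis, cholesterol synthesis, Hox, ERK, p53 and fibroblast lists passed by camera with each sample left out, and no list past the threshold reversed.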

Other observations

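All tests of explanations in this part, the counts over splits and the added gene lists were chosen only after the results were seen. Within the Hox list a rise was seen in 2 of the 4 clusters, and it is not excluded in the others. All 10 measured Hoxb genes were higher, with a median of 1.45, and 9 rose when adjusted over the list alone (camera adjusted p = 3.42e-10 over the 7 added lists, and adjusted p = 0.144 with an estimated correlation). All 7 Hoxc genes were higher, with a median of 0.89 and 4 rises when adjusted over the list alone (camera adjusted p = 0.000156, and adjusted p = 0.144 with an estimated correlation). The 9 Hoxa genes had a median of -0.18 (camera adjusted p = 0.783) and the 7 Hoxd genes 0.11 (adjusted p = 0.680). These signs held under all 4 other scalings. Hoxb and Hoxc medians were positive in all 3 same-numbered pairs and both slide rows. Hoxa medians were -0.602, 1.15 and -0.244 in the pairs, and Hoxd medians -0.18, 0.318 and -0.662. Both changed sign between slide rows as well. Most Hoxa and Hoxd probes were dim, with standard errors of up to 0.96 and 1.11. Hoxb1 was not well above background in any vehicle sample. The difference between clusters was not tested.

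Targets of hypoxia-inducible factor (HIF) outside the glycolysis list had a median of -0.31 over 29 genes, with 24 negative and 11 falls when adjusted over the list alone (camera adjusted p = 1.86e-05, and adjusted p = 0.144 with an estimated correlation). A list of 30 mitochondrial genes held oxidative phosphorylation genes and citric acid cycle enzymes such as Cs and Aco2. Its median was -0.08 (camera adjusted p = 0.425), near the -0.06 of all tested genes. The fall in glucose breakdown genes thus had no counterpart there that the test could see.

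The Sall4 probes disagreed in direction. Slide column as a covariate left probe A_51_P145260 at -1.05 (SE 0.118), which argued against array signal level as the cause of that probe's fall. For A_55_P2173546 array signal level stays open. Its tamoxifen signal was highest in slide column 1 and lowest in column 4, and not well above background in 2 of the 3 samples. All 9 of 9 same-numbered differences had the sign of their probe's mean (2 of them on signal not well above background). They come from 3 probes of 1 gene on the same arrays and are not independent. A wrong label could leave a difference near 0 with either sign, so the signs alone are weak. Sizes say more: 1.103, 0.86 and 0.95 for the brightest probe (SD 0.03 in vehicle, 0.15 in tamoxifen) and -1.26, -0.76 and -1.44 for A_51_P145260 (SD 0.05 and 0.32). None was near 0, which argued against a wrong label of a single sample or an exchange of 1 sample per group. An exchange of the whole groups would give the same sizes and stays open. The number of Sall4 probes that could be placed inside or outside the deleted part was 0, so that reading could be neither supported nor excluded.

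The Hox rise could come from feeder fibroblasts that passed the EpCAM sort, since fibroblasts express Hox genes. The fibroblast marker median was 0.32, with a bootstrap interval of 0.16 to 0.386, against 0.155 to 1.15 for the whole Hox list. These overlap. The Hoxb genes, set apart only after the results were seen, had an interval of 1.21 to 1.68, above that of the markers. The bootstrap resampled genes, so no interval measures the spread between cultures. Markers with a high level in vehicle samples would hide a small share, so feeder RNA stays open. Slide column as a covariate left the Hox median at 0.564, so a linear trend over slide columns did not remove the rise. Camera called 17 lists under that covariate, and a split other than treatment reached a Hox median of 0.563 in size. The kept call therefore separates little, and array signal level stays open. Loss of Sall4 and exposure to the drug or to active Cre stay open and cannot be told apart in this design.

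The fall of glycolysis genes could reflect a loss of signal among bright genes or lower HIF activity. Among random gene lists of matched level the share with a median as low was 1e-04, the smallest that 10000 draws can give, which argued against the former. HIF targets outside glycolysis and not past the threshold on their own had a median of -0.278 over 27 genes (camera adjusted p = 0.000336, and adjusted p = 0.144 with an estimated correlation), so lower HIF activity stays open. By the same matched lists, 7.76% and 3.75% had medians as low as those of DNA repair and heat shock genes.

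The 6 samples can be parted into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 149 changed genes and 100 of at least 2-fold, the highest other split 0 and 0 (limma, at most 4056 genes at unadjusted p under 0.05, in the split that follows slide column), so 1 of 10 splits reached each count, and 1 of the 4 that part all 3 same-numbered pairs. For shifted lists the real split gave 11 and the highest other 19, in the split that follows slide row. At least 11 came from 4 of 10 splits, and from 3 of the 4 that part all pairs. The number of shifted lists therefore did not set the treatment apart. Every other split still divides the treatments unequally, so its lists hold part of any treatment effect. The rest of that effect widens the spread within its groups, which lowers its gene count. Neither count is thus a reference free of treatment. Glycolysis had a smaller camera p in the real split (5.64e-14) than in any other (1.86e-06), as had p53 targets (5.17e-06 against 8.72e-05). The other 9 shifted lists had a smaller p in some other split, among them Hox (1.28e-11 against 1.19e-07), ERK (1.63e-09 against 1.02e-07), cholesterol (1.89e-11, by slide row, against 4.97e-06) and fibroblast genes (4.7e-08 against 2.98e-07), and for proliferation genes 7 of 10 splits, the real one included, had a p as small. The median was largest in size in the real split for 10 of the 11 lists, such as ERK (0.36 against at most 0.24), Hox (0.62 against 0.56) and cholesterol (-0.31 against a size of 0.21), proliferation being the exception.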
